A study of Pseudomonas aeruginosa PAO1 with 28 samples.

How the data were processed

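Transcripts of Pseudomonas aeruginosa PAO1 were measured on the Affymetrix P. aeruginosa genome array with 1 array per transition and time, 28 in all. Per the labels' protocols, samples of the chemostat were stabilised at once, total RNA was extracted with an on-column DNase step, and fragmented cDNA was labelled with biotin. The deposited values are linear intensities per probe set, made with MAS5 per the submitters' processing notes; its version, scale target and filters were not given in the sources used here. On each of the 28 arrays the mean of the deposited intensities without the lowest and highest 2% of probe sets was between 150.07 and 150.3, so the arrays had been scaled to 1 level. Such scaling moves all genes of an array together, and a rise of dim probe sets then lowers the bright ones. A signal of 0 made up 0.07% of the values. No pair of arrays shared more than 0.93% identical values, so each was counted as 1 sample.

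Of 5896 probe sets, 5545 stood for a gene, 199 for an intergenic region, 135 for a gene of another strain, 3 for rRNA and 14 for controls. Locus tags and symbols came from the probe sets' names and the platform annotation, which gives 1 symbol for 5500 gene probe sets. Of the gene loci, 5504 matched the RefSeq table of assembly ASM676v1, which was used for names and neighbours only. No genome build was given for the array, and no coordinates are reported.

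Groups and times came from the labels. The replicate numbers only name the arrays of a transition in order, so that high-to-low replicate 1 is the 0 min array. Values were log2(signal + 16), and fold changes are on that scale, which understates changes of dim genes. Limma 3.58.1 in R 4.3.3 fitted a natural spline of time with 3 df per transition to all 28 arrays (20 residual df, eBayes with trend). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 5545 genes, by an F test of the 3 spline terms of a transition or of their differences. The size of a shift is the fitted mean of 50, 60, 70, 80 and 90 min minus the fitted value at 0 min, and a called gene is termed higher or lower by its sign; a gene that rose and came back can be called with a small change. The sum of both changes was tested as a contrast. Low and high oxygen were compared on 12 arrays with the transition as covariate (9 residual df): high-to-low at 50 to 90 min and low-to-high at 0 min against low-to-high at 50 to 90 min and high-to-low at 0 min. Signals of single genes are given with the SD over 6 arrays.

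Before the data were examined, 26 gene lists with 409 members were fixed from textbook knowledge, and 400 members had a usable probe set. They were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the 26 lists. Named genes followed a rule fixed at the same time: the 12 largest rises and 12 largest falls between low and high oxygen among called genes with mirrored measured changes, up to 4 called members per list with the largest change (or the 2 brightest where 0 passed), the 5 largest rises and falls of each shift and of the sum, the 5 largest F values of the difference, and anr, dnr, narL and narX.

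The fits were tested on simulated data for 5545 genes with 50 changed genes of each size. For changes of 0.5, 1, 2 and 4 on the log2 scale, the shift to low oxygen recovered 4, 22, 47 and 50, the shift to high oxygen 3, 29, 48 and 50, and low versus high oxygen 2, 26, 49 and 50. False calls were 4 of 127, 5 of 135 and 6 of 133. The simulated scatter had no raised arrays and no change of level between arrays.

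Alternatives planned beforehand were quantile normalization, median centring, pseudocounts of 1 and 64, the dimmest 25% of probe sets left out, eBayes without trend or robust, splines of 2 and 4 df, a log2 time axis with an offset of 5 min, each transition fitted alone, other sets of arrays for low versus high oxygen, and each array left out in turn. Chosen after the data were seen were the fits without the 8 raised arrays, with the intergenic median subtracted, and with its log2 as a covariate, the matching correlations, and the list tests of the sum of both changes. The limit of 30 for a raised array was also set after the intergenic medians were seen, in place of a rule by the widest gap that would have marked fewer arrays. Figures were drawn with matplotlib 3.10.9.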

Results

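The data followed the transcripts of Pseudomonas aeruginosa PAO1, a widely used laboratory strain of this bacterium, in a continuous culture whose oxygen supply was changed in both directions. In the transition from high to low oxygen, the set point of the oxygen tension (pO2) went from 100% to 0.5%. After a steady state at low oxygen the same culture was returned from 0.5% to 100%. Each transition was sampled at 14 times, every 5 min from 0 to 40 min and every 10 min from there to 90 min. There was 1 Affymetrix array per time, which makes 28 arrays. The stated aim was to find genes that respond to oxygen and the regulatory network behind them. The table held MAS5 signals of 5896 probe sets, of which 5545 stood for 1 gene each. There were no replicate arrays, so in the fits over time the spread came from the scatter about a smooth course in 1 culture. Between low and high oxygen it came from the scatter of 12 arrays about constant levels for oxygen and transition. Most of those 12 were successive samples of the culture from 50 to 90 min, treated as replicates, so trends in time entered that spread. The p-values measured only such scatter and not the spread between cultures. The number of arrays limited the precision.

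The 28 arrays were not alike in the signal of 199 probe sets for intergenic regions. On 20 arrays their median signal lay between 15.6 and 27.3, and on 8 arrays it lay between 33.1 and 69.6. These 8 arrays, called raised arrays here, were high-to-low at 40, 50, 70, 80 and 90 min and low-to-high at 5, 60 and 70 min. The 25th percentile of the gene signals was 46.5 to 87.0 on the raised arrays and 23.1 to 43.2 on the others. Of the 5 arrays from 50 to 90 min, 4 were raised at low oxygen and 2 at high oxygen. Relative to the other 20 arrays, the dimmest 25% of genes were higher on the raised arrays by a median of 0.99 on the log2 scale, and the brightest 10% were lower, with a median difference of -0.41.

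**Figure D1:**
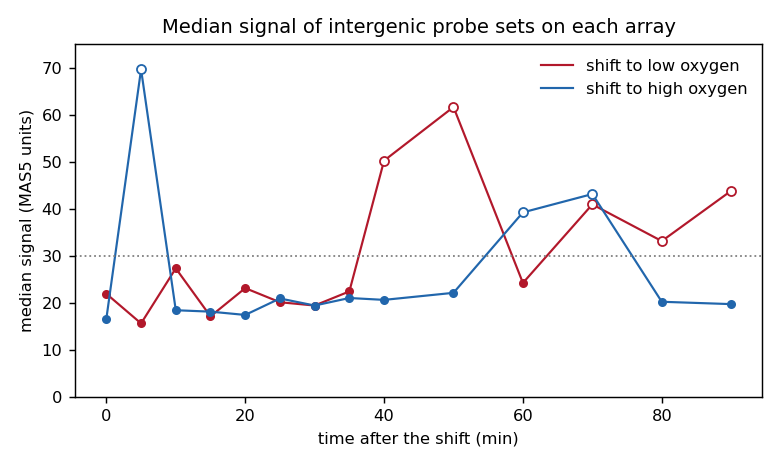
Median signal (MAS5 units) of 199 intergenic probe sets on each array against the time after the shift (min), in red for the shift to low oxygen and in blue for the shift to high oxygen. Open circles mark the 8 arrays above the dotted line at 30, which span 33.1 to 69.6; filled circles are the other 20, which span 15.6 to 27.3.

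The first comparison asked which genes differed between low and high oxygen over the arrays of both transitions. It fitted 1 oxygen effect for both, so a gene could pass mainly through 1 transition. The second cbb3-type terminal oxidase, an enzyme that reduces oxygen at the end of the respiratory chain, had the largest rises at low oxygen. Its gene ccoN2 had a signal of 2016 ± 599 at low oxygen and 44.5 ± 16.3 at high oxygen (SD, n = 6 arrays each), a log2 difference of 4.69 ± 0.26 (SE). The differences were 5.40 ± 0.30 for ccoO2 and 4.78 ± 0.29 for ccoP2. The denitrification genes nirS, the cytochrome cd1 nitrite reductase, and nirC rose by 3.02 ± 0.48 and 3.31 ± 0.54, while genes for the siderophore pyoverdine fell, with differences of -2.05 ± 0.37 for its receptor gene fpvA and -1.58 ± 0.26 for its synthesis gene pvdA. The signal of nirC lay below the intergenic median on each of the 4 unraised arrays at high oxygen (9.9 to 13.2 against 19.7 to 22.1), so the size of its changes is uncertain. On the same arrays ccoO2 (26.9 to 30.8) and nirS (25.8 to 33.6) lay just above it, which also limits the sizes of their differences. Limma's moderated test called 76 of 5545 genes after Benjamini-Hochberg adjustment, 50 higher and 26 lower at low oxygen. All 76 had measured changes of opposite sign in the 2 shifts. The tested difference is built from these same changes, so the selection favours opposite signs and this is no separate support. Of the 76 genes, 73 were also called after the shift to low oxygen and 30 after the shift to high oxygen. The adjusted p was 1.54e-07 for ccoN2, 0.0045 for nirS and 0.00934 for fpvA. The count rested on the 0 min arrays. It was 451 without the low-to-high one, 207 higher and 244 lower, so that the larger direction turned. Without the high-to-low one it was 17, and the calls of nirS (log2 1.91, adjusted p = 0.224), nirC (2.13, adjusted p = 0.238), fpvA (-1.09, adjusted p = 0.401) and pvdA (-1.25, adjusted p = 0.229) ended. Without the 8 raised arrays, which left 6 of the 12, limma called 13 genes, 7 of them among the 76; those of the second cbb3 oxidase were called, and nirS (3.33, adjusted p = 0.0996) and fpvA (-2.22, adjusted p = 0.193) were not. Lower calls also outnumbered higher ones without the transition term (270 higher and 387 lower), on late arrays blocked by time (331 and 495) and with the intergenic median as a covariate (80 and 83).

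Among the other genes with the largest rises, oprG, an outer membrane protein, had a log2 difference of 3.47 ± 0.24 and hemN, an oxygen-independent enzyme of heme synthesis, 3.37 ± 0.29. The cytochrome c peroxidase gene ccpR rose by 3.15 ± 0.56. The loci PA5475, PA1673, PA2119, PA0141 and PA1746 rose by 4.24, 3.90, 3.35, 3.26 and 3.24. On the 4 unraised arrays at high oxygen PA2119 lay below the intergenic median on 3 and PA5475 on 2, which leaves the size of their changes uncertain. The largest fall was that of PA3530, from a signal of 319 ± 46.1 at high oxygen to 44.2 ± 18.9 at low oxygen (log2 -2.43 ± 0.27); 1 of the 2 unraised arrays at low oxygen had it below the intergenic median. PA0315, PA2378 and PA2379 had differences of -1.85, -1.83 and -1.65, PA0227 and its neighbour pcaF of -1.55 and -1.40, and PA4910, PA2404 and PA2412 of -1.29, -1.25 and -1.20. At low oxygen on the low-to-high 0 min array, PA0227 and pcaF had signals of 499.5 and 251.3. These were above the 413 and 226.2 at high oxygen on the high-to-low 0 min array. Without the high-to-low 0 min array the calls of ccpR (1.40), PA2119 (2.16), PA0141 (2.14) and PA1746 (2.02) ended, and so did those of PA0315 (-0.66), PA2378 (-0.81), PA2379 (-0.76), PA0227 (-0.58), pcaF (-0.57), PA4910 (-0.51), PA2404 (-0.69) and PA2412 (-1.17). With the intergenic median subtracted on each array, fpvA, PA0315, PA2379, PA0227, pcaF, PA4910 and PA2404 did not pass either. In the fit without the raised arrays, with 6 of the 12 arrays left, oprG, hemN and PA3530 passed and the other genes of this paragraph did not. Their differences there were 3.29 for ccpR to 4.57 for PA5475 among the rising genes, and -2.22 for fpvA to -1.25 for PA4910 among the falling ones.

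Of the 27 genes listed as associated with Anr, the global regulator of anaerobic metabolism, 18 rose, 0 fell and 9 did not pass, with 24 higher when adjusted over the list alone (median log2 2.39, camera adjusted p = 1.49e-53, adjusted p = 0.0503 with an estimated correlation). Denitrification had 8 higher, 0 lower and 27 not called of 35, with 14 higher when adjusted over the list alone (median 0.84, camera adjusted p = 2.79e-21, adjusted p = 0.0739 with an estimated correlation). All 3 genes of the second cbb3 oxidase rose, also when adjusted over the list alone. This was the 1 list that camera called with an estimated correlation (adjusted p = 0.0065). Fry called 11 of the 26 lists, among them the Anr-associated genes (fry adjusted p = 0.00399) and denitrification (fry adjusted p = 0.0379). In the first cbb3 oxidase 0 of 3 genes passed, also when adjusted over the list alone, with a signal of 1021 ± 272 at low and 1020 ± 122 at high oxygen for ccoN1. Of 8 regulators of the oxygen and nitrate response, 2 rose, or 5 adjusted over the list alone: dnr by 2.70 ± 0.40 and narL by 1.67 ± 0.28 (camera adjusted p = 1.25e-09, adjusted p = 0.0507 with an estimated correlation). Without the high-to-low 0 min array their values were 1.98 and 0.95 and did not pass. The differences of anr (0.86 ± 0.24, adjusted p = 0.129) and narX (1.08 ± 0.34, adjusted p = 0.203) did not pass. In the arginine deiminase pathway, a fermentative route to ATP, arcC rose by 1.92 ± 0.37, the 1 call of 4, or 4 adjusted over the list alone (adjusted p = 0.0739 with an estimated correlation). Without the raised arrays the medians were 2.75 for the Anr-associated genes, 0.94 for denitrification, 1.05 for the regulators and 1.71 for arginine deiminase. There dnr (3.08), narL (1.80) and arcC (2.24) did not pass with fewer arrays. The signal of dnr lay below the intergenic median on 2 of the 4 unraised arrays at high oxygen. Leaving out the high-to-low or the low-to-high 0 min array gave medians of 1.21 and 3.32 for the Anr-associated genes, 0.39 and 1.65 for denitrification, and 0.33 and 1.41 for the regulators. The first cbb3 oxidase (0.51, adjusted p = 0.00354) passed camera without the first of these arrays and had -0.28 without the second.

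Of the pyruvate and lactate genes, 2 of 8 rose, or 4 adjusted over the list alone, among them the alcohol dehydrogenase adhA by 3.13 ± 0.41 and the acetate kinase ackA by 1.17 ± 0.25 (adjusted p = 0.0507 with an estimated correlation). The ribonucleotide reductase gene nrdJb rose by 1.25 ± 0.29, 1 of 6, or 2 adjusted over the list alone (adjusted p = 0.0507 with an estimated correlation), and in heme biosynthesis hemN and hemB (0.99 ± 0.22) rose, 2 of 9 by either adjustment (adjusted p = 0.0739 with an estimated correlation). The hydrogen cyanide genes hcnA (1.19 ± 0.28, adjusted p = 0.0573) and hcnB did not pass over all genes, while 3 of 3 passed when adjusted over the list alone (adjusted p = 0.0739 with an estimated correlation). Pyoverdine had 3 of 18 genes lower, fpvA, pvdA and its sigma factor pvdS (-1.50 ± 0.34), or 12 adjusted over the list alone (median -0.81, camera adjusted p = 1.95e-14, adjusted p = 0.0739 with an estimated correlation). In oxidative stress defence, ahpF, a subunit of alkyl hydroperoxide reductase, fell (-0.99 ± 0.14), the 1 call of 18 by either adjustment (camera adjusted p = 0.0472, adjusted p = 0.151 with an estimated correlation). Without the high-to-low 0 min array the calls of adhA (2.11), ackA (0.85), nrdJb (0.89), arcC (1.65), hemB (0.37), pvdS (-1.82) and ahpF (-0.88) ended. Without the raised arrays the medians were -1.02 for pyoverdine and -0.29 for oxidative stress defence, and the second list did not pass camera (adjusted p = 0.149). With fewer arrays adhA (3.395), ackA (1.34), nrdJb (1.49), hemB (0.88), pvdS (-2.00) and ahpF (-0.999) did not pass, while hcnA (1.30) and hcnB (1.16) did. The list medians without the high-to-low and without the low-to-high 0 min array were 0.19 and 1.40 for pyruvate and lactate, 0.52 and 1.01 for ribonucleotide reductases, 0.01 and 0.41 for heme biosynthesis, -1.09 and -0.50 for pyoverdine, and -0.38 and -0.05 for oxidative stress defence. Leaving out the second of these arrays ended the camera calls of ribonucleotide reductases (adjusted p = 0.117), hydrogen cyanide synthesis (0.83, adjusted p = 0.168) and oxidative stress defence (adjusted p = 0.404). The call of oxidative stress defence also ended without the high-to-low 70 or 90 min array or the low-to-high 50, 80 or 90 min array, with adjusted p from 0.0529 to 0.0775.

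Some lists passed camera with 0 single genes called, over all genes or adjusted over the list alone. The medians were 0.40 for NADH dehydrogenase I (adjusted p = 0.285 with an estimated correlation), 0.29 for ATP synthase (adjusted p = 0.428 with an estimated correlation), 0.24 for cytochrome c maturation (adjusted p = 0.365 with an estimated correlation) and 0.18 for the flagellum (adjusted p = 0.557 with an estimated correlation). They were -0.59 for phenazines (adjusted p = 0.619 with an estimated correlation) and -0.43 for quorum sensing and exoproducts (adjusted p = 0.552 with an estimated correlation), and without the high-to-low 0 min array these were 0.37 and 0.23, and without the low-to-high one -1.61 and -1.25. Phenazines also did not pass camera without the high-to-low 50, 60 or 70 min array or the low-to-high 50 min array (adjusted p from 0.057 to 0.0777). The call of cytochrome c maturation ended without the high-to-low 0 min array (0.17, adjusted p = 0.16; 0.62 without the low-to-high one). Those of ATP synthase (0.02, adjusted p = 0.612) and the flagellum (0.21, adjusted p = 0.45) ended without the low-to-high 0 min array, and ATP synthase had 0.47 without the high-to-low one. The tricarboxylic acid (TCA) cycle (0.12), heat shock genes (0.19), type III secretion (-0.02), R- and F-type pyocins (0.01), pyochelin (0.06), other iron uptake (-0.19), other terminal oxidases (0.35) and ribosomal proteins (0.00) did not pass camera. Of these, the TCA cycle (0.27), other iron uptake (-0.70), heat shock genes (0.26) and ribosomal proteins (0.18) passed without the high-to-low 0 min array. Without single 0 min arrays the medians went from -0.43 to 1.13 for other terminal oxidases, -0.65 to 0.68 for pyochelin, -0.70 to 0.44 for other iron uptake, -0.37 to 0.36 for type III secretion, -0.26 to 0.23 for pyocins. They went from -0.14 to 0.18 for ribosomal proteins and -0.08 to 0.27 for the TCA cycle. The signs of these 7 medians were not settled. In the lists of other terminal oxidases and other iron uptake 1 gene each was lower when adjusted over the list alone. Camera directions opposed the medians for other terminal oxidases (down) and type III secretion (up). Without the raised arrays phenazines (-0.54, adjusted p = 0.43) and quorum sensing (-0.30, adjusted p = 0.761) did not pass, while the TCA cycle (0.17), heat shock genes (0.55) and ribosomal proteins (0.04) passed camera. The aa3-type oxidase genes coxA (-1.34 ± 0.60, adjusted p = 0.469) and coxB did not pass over all genes.

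**Figure D2:**
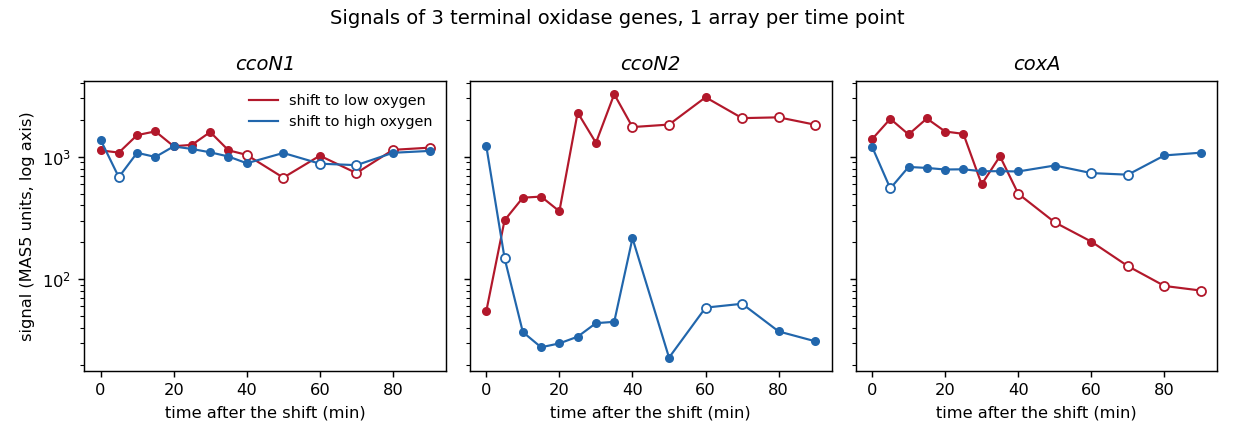
Signals (MAS5 units, log axis) of ccoN1, ccoN2 and coxA against the time after the shift (min), 1 array per point, in red for the shift to low and in blue for the shift to high oxygen; open circles are the raised arrays. The signal of ccoN2 went from 54.5 to 1824 in the shift to low oxygen and from 1223 to 31.0 in the other, while coxA went from 1387 to 80.5 in the shift to low oxygen and was 1209 at the start of the other.

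After the shift to low oxygen the largest rises were those of 2 genes of the second cbb3 oxidase, 5.48 ± 0.60 for ccoO2 and 5.44 ± 0.48 for ccoP2, and the third, ccoN2, rose by 4.38 ± 0.62 (fitted mean of 50 to 90 min minus fitted 0 min value, log2 ± SE). The peroxidase gene ccpR rose by 5.29 ± 0.37, PA5475 by 4.75 ± 0.57 and nirC by 4.69 ± 0.47. The largest falls were those of PA3923 (-4.88 ± 0.40), PA3922 (-4.76 ± 0.33), icmP (-4.41 ± 0.37), PA1215 (-4.30 ± 0.29) and PA2939 (-4.15 ± 0.44). A fit without the raised arrays extrapolates from the 60 min array. It gave 5.01 for ccoO2, 3.95 for ccoP2, 2.14 for ccpR, 4.91 for PA5475 and 1.98 for nirC, and -1.10 for PA3923, -0.70 for PA3922, -0.05 for icmP, -2.15 for PA1215 and 1.81 for PA2939, each still called by the F test. PA2939 had signals of 762 at 0 min and 71.0 at 60 min. The signal of coxA fell from 1387 at 0 min to 80.5 at 90 min (-3.38 ± 0.25). Limma's F test called 2902 genes (52.3%), of which 1712 ended higher and 1190 lower. Permuted times within the transition gave up to 2661 calls. The fit shared 1 spread per gene between the transitions, while the median residual SD was 0.368 in high-to-low and 0.25 in low-to-high. This favours calls in the shift to low oxygen, so the counts of the 2 shifts cannot be compared directly. Fitted alone, with fewer residual df, the high-to-low arrays gave fewer calls. The median change of all genes was 0.25, against 0.05 after quantile normalization and -0.08 with the intergenic median subtracted on each array. With that subtraction 1025 of 2822 called genes ended higher and 1797 lower, so that the larger direction turned, and with the intergenic median as a covariate the split was 1306 to 1834.

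Denitrification genes ended higher in 31 of 35 cases, with 32 adjusted over the list alone (median 1.72, adjusted p = 0.0894 with an estimated correlation), and Anr-associated genes in 26 of 27 by either adjustment (median 3.09, adjusted p = 0.0856 with an estimated correlation). The second cbb3 oxidase had 3 of 3 higher by either adjustment (adjusted p = 0.0856 with an estimated correlation). The first cbb3 oxidase had 3 of 3 lower by either adjustment (median -0.475), but did not pass camera (adjusted p = 0.148). Its measured median was 0.81 above the 0 min array at 15 min and 0.07 above it at 90 min. Fitted without the raised arrays the median change was 0.19, so a fall of these genes was not settled. Other terminal oxidases had 5 higher and 4 lower of 9 by either adjustment and did not pass camera (adjusted p = 0.645). Of the regulators, 7 of 8 ended higher by either adjustment, anr by 1.38 ± 0.28 and narX by 1.86 ± 0.23 (adjusted p = 0.0377 with an estimated correlation), and of the pyruvate and lactate genes 5 of 8 by either adjustment (adjusted p = 0.0434 with an estimated correlation). Cytochrome c maturation had 9 of 9 higher by either adjustment (adjusted p = 0.353 with an estimated correlation), heme biosynthesis 7 higher and 1 lower of 9 (adjusted p = 0.0668 with an estimated correlation), and arginine deiminase 4 of 4 higher (adjusted p = 0.506 with an estimated correlation), with the same counts adjusted over the list alone. Among the lists camera called lower, phenazines, redox-active secreted pigments, had 9 of 10 genes lower by either adjustment (median -1.98, adjusted p = 0.0894 with an estimated correlation). Quorum sensing and exoproducts had 18 lower and 1 higher of 21 by either adjustment, among them the lectin gene lecB (-1.55 ± 0.33; list median -1.55, adjusted p = 0.0894 with an estimated correlation). Pyoverdine had 11 of 18 lower by either adjustment (median -1.25, adjusted p = 0.275 with an estimated correlation). The TCA cycle had 11 lower and 2 higher of 18, with 12 lower adjusted over the list alone (median -0.48, adjusted p = 0.722 with an estimated correlation). Ribosomal proteins had 8 lower and 6 higher of 53, with 5 lower and 2 higher adjusted over the list alone (median -0.21, adjusted p = 0.947 with an estimated correlation), and their median turned to 0.15 after quantile normalization. Camera directions opposed the medians in 6 lists: other terminal oxidases, hydrogen cyanide synthesis, ATP synthase, oxidative stress defence, other iron uptake and pyocins. In a fit without the raised arrays the late change rested on the 60 min array and an extrapolation, and there the medians of phenazines (1.92), quorum sensing (0.33), pyoverdine (0.73), the TCA cycle (1.26) and ribosomal proteins (0.87) had the other sign. The same fit ended the camera calls of denitrification (0.59, adjusted p = 0.181), the regulators (0.44, adjusted p = 0.647), the second cbb3 oxidase (3.95, adjusted p = 0.133), cytochrome c maturation (0.59, adjusted p = 0.254) and heme biosynthesis (0.17, adjusted p = 0.817). Anr-associated genes (2.24), pyruvate and lactate (2.23) and arginine deiminase (2.35) passed with the same sign.

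Measured on the unraised 60 min array against the 0 min array, the list medians were 5.99 for the second cbb3 oxidase, 4.27 for Anr-associated genes, 1.80 for denitrification, -1.81 for phenazines, -1.07 for quorum sensing, -1.05 for pyoverdine, 0.16 for the TCA cycle and 0.09 for ribosomal proteins. In time, the called members of the second cbb3 oxidase passed 50% of their late log2 change at 10 min, those of the Anr-associated list at 20 min, pyoverdine at 25 min and denitrification at 35 min. In signal the rise of ccoO2 came later, with 535 at 10 min, 2688 at 25 min and 2213 at 90 min. After the return to high oxygen the 50% times of the 4 lists, in the same order, were 5 min, 5 min, 30 min and 10 min. The 5 min array of the return was the most raised of all, with an intergenic median of 69.6. There nirC had a signal of 153 between 175 at 0 min and 8.3 at 10 min, and nirS 160 between 211 and 26.4, so the 5 and 10 min times do not order the lists. These times describe 1 culture and have no test. From the mean of 0 and 5 min as start, the Anr-associated list moved to 25 and 10 min, the second cbb3 oxidase to 10 min in the return and pyoverdine to 35 min in the return.

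**Figure D3:**
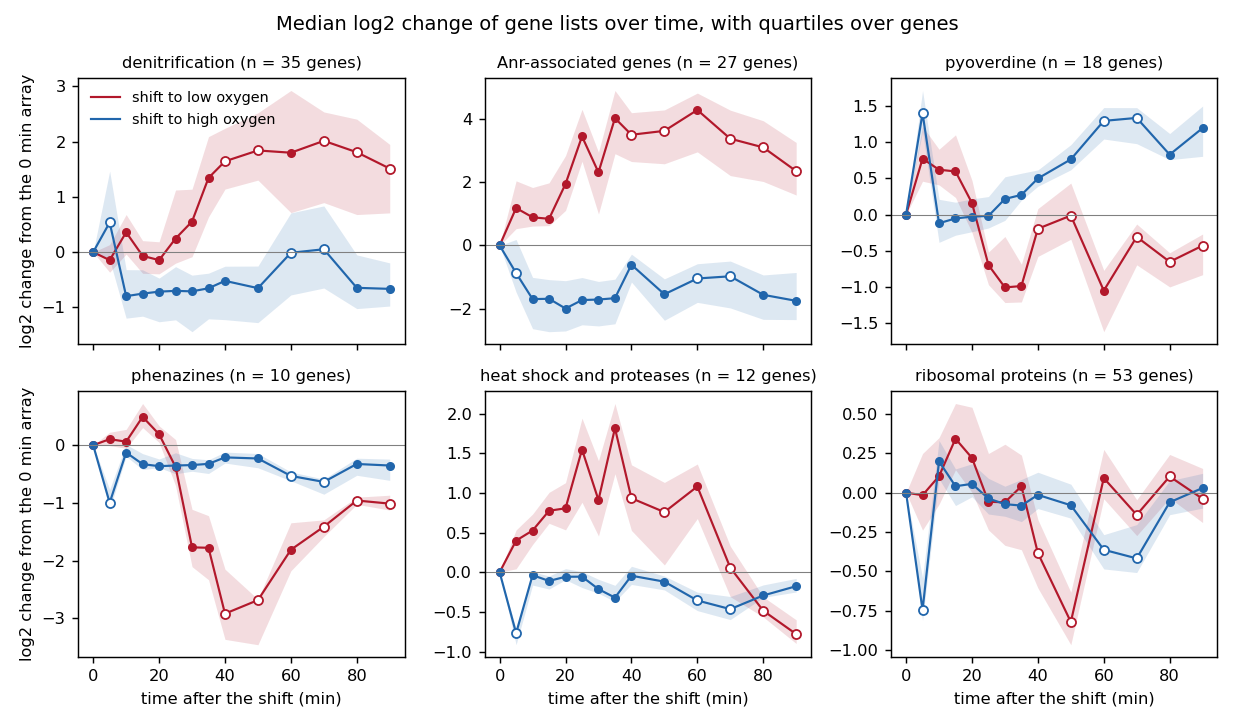
Median log2 change from the 0 min array against the time after the shift (min) for 6 gene lists, with the quartiles over genes shaded, in red for the shift to low and in blue for the shift to high oxygen. Open circles are the raised arrays. Anr-associated genes peak at 4.27 at 60 min and heat shock genes at 1.82 at 35 min in the shift to low oxygen.

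After the return to high oxygen, the second cbb3 oxidase genes fell most, with fitted changes of -3.17 ± 0.60 for ccoO2, -2.95 ± 0.48 for ccoP2 and -2.78 ± 0.62 for ccoN2. The signal of ccoN2 went from 1223 at 0 min to 148 at 5 min and 36.9 at 10 min. Genes of protocatechuate 3,4-dioxygenase, which opens an aromatic ring, also fell, with changes of -2.48 ± 0.46 for pcaG and -2.31 ± 0.53 for pcaH. The gene pcaG had a signal of 1862 at 0 min and 81.4 at 10 min. The largest rises were in PA2310 (2.56 ± 0.43) and in the neighbouring loci PA3441 (2.92 ± 0.34), PA3442 (2.51 ± 0.40), PA3443 (2.53 ± 0.37) and PA3444 (2.50 ± 0.43). The signal of PA3441 was 197 at 0 min, 1175 at 40 min and 682 at 90 min. Limma's F test called 110 genes, 76 higher and 34 lower late in the transition. The spread shared with the other transition was in the median wider than the scatter of these arrays, which lowers this count. The smooth course lagged behind falls completed within 10 min, so that ccoO2 had a fitted change of -3.17 and a measured one of -4.89. The count was 44 with a spline of 2 df (43 higher and 1 lower), where these 5 falls did not pass, and 395 with the low-to-high arrays fitted alone. It was 226 without the low-to-high 0 min array, 82 higher and 144 lower, so that the larger direction turned. Without that array the calls of these 5 falling genes ended, with values of -1.29 for ccoO2, -1.42 for ccoP2, -1.01 for ccoN2, -0.91 for pcaG and -0.48 for pcaH. In the fit without the raised arrays the call of ccoN2 ended (-2.95, adjusted p = 0.116). Of the 10 genes named for this shift, 2 lost the call after median centring, 2 with the intergenic median subtracted and 1 after quantile normalization.

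In this shift denitrification had 11 of 35 genes lower, with 19 adjusted over the list alone (median -0.57, adjusted p = 0.0615 with an estimated correlation), and Anr-associated genes 4 of 27, with 13 adjusted over the list alone (median -0.90, adjusted p = 0.0615 with an estimated correlation). The second cbb3 oxidase had 3 of 3 lower by either adjustment (adjusted p = 0.0066 with an estimated correlation). Arginine deiminase had 1 of 4 lower, or 4 adjusted over the list alone (median -0.96, adjusted p = 0.0425 with an estimated correlation). The regulators had 1 of 8 lower, or 2 adjusted over the list alone (adjusted p = 0.0588 with an estimated correlation), and hydrogen cyanide synthesis 0 of 3 (median -0.77, adjusted p = 0.208 with an estimated correlation). Oxidative stress defence had 2 of 18 higher by either adjustment (median 0.17, adjusted p = 0.0425 with an estimated correlation). Pyoverdine had 2 of 18 higher, or 12 adjusted over the list alone (median 0.45, adjusted p = 0.329 with an estimated correlation). Camera also called R- and F-type pyocins (-0.27, adjusted p = 0.837 with an estimated correlation), quorum sensing (0.12, adjusted p = 0.837 with an estimated correlation) and ribosomal proteins (0.09, adjusted p = 0.854 with an estimated correlation), with 0 single genes called; the ribosomal median turned to -0.03 after quantile normalization. Without the raised arrays the medians of quorum sensing (-0.10) and ribosomal proteins (-0.12) had the other sign, that of pyoverdine was 1.03, and camera did not call oxidative stress defence (0.20, adjusted p = 0.0988) or pyocins (0.01, adjusted p = 0.322). Camera directions opposed the medians for the TCA cycle, other terminal oxidases and other iron uptake.

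The last comparison asked whether the return mirrored the first shift. For coxA it did not: the gene changed by -3.38 ± 0.25 in the shift to low oxygen and by -0.01 ± 0.25 in the return, a sum of -3.39 ± 0.35 where an equal return gives 0 (adjusted p = 1.95e-07). The largest negative sums were those of PA3923 (-4.97 ± 0.56), PA3922 (-4.69 ± 0.47), PA2939 (-4.50 ± 0.62), PA3516 (-4.16 ± 0.49) and PA1914 (-4.03 ± 0.46), and the largest positive ones those of PA3431 (4.06 ± 0.78), ccpR (3.95 ± 0.52), PA2310 (3.81 ± 0.60), PA3444 (3.23 ± 0.61) and PA3446 (3.22 ± 0.59). Fitted without the raised arrays, and so extrapolated from 60 min at low oxygen, these sums did not pass. That of coxA was -3.09 (adjusted p = 0.201, from changes of -2.85 and -0.25). Those of the other genes were -1.51 for PA3923, -0.84 for PA3922, 1.19 for PA2939, -1.21 for PA3516 and -1.57 for PA1914, and 1.43 for PA3431, 0.90 for ccpR, 4.08 for PA2310, 3.27 for PA3444 and 0.004 for PA3446, with adjusted p from 0.284 to 1. Measured on unraised arrays alone, with no test, the sum was -2.99 for coxA and lay between -5.08 and -3.73 for the 5 negative and between 1.58 and 4.49 for the 5 positive genes. At 0 min of the shift to low oxygen PA2310 (6.3) and PA3444 (20.4) lay below the intergenic median of 21.9, and PA3431 (22.6) lay just above it. The sizes of the sums of PA2310, PA3444 and PA3431 are therefore uncertain. The signal of PA3923 fell from 1185 to 61.7 in 90 min of low oxygen and stood at 1201 at the start of the return, after the steady state at low oxygen. Limma called 641 genes for such a sum, 276 positive and 365 negative. It called 1158 genes for a different course. That test also calls a gene with an equal and opposite return, so its count does not measure a lack of mirroring. The largest F was that of PA3690 (106), whose signal rose from 176 at 0 min to 2519 at 25 min and ended at 103 in the shift to low oxygen, and lay between 154 and 212 in the return. Of the lists, tested for the sum of both changes after the data were seen, camera called 6 positive and 4 negative, and 0 with an estimated correlation. Fry called 8. Anr-associated genes had 17 of 27 positive, with 20 adjusted over the list alone (adjusted p = 0.229 with an estimated correlation), phenazines 8 of 10 negative, with 9 adjusted over the list alone (adjusted p = 0.129 with an estimated correlation), and denitrification 12 of 35 positive, with 16 adjusted over the list alone (adjusted p = 0.458 with an estimated correlation). The count of 641 was 72 without the raised arrays (42 positive and 30 negative), 347 with a spline of 4 df (112 and 235), 237 on a log time axis (56 and 181) and 1076 after quantile normalization. It was 1013 without the low-to-high 5 min array, with 572 positive and 441 negative. The larger direction turned there, as it did without the raised arrays. The count was 419 without the low-to-high 0 min array. Positive sums fell more than negative ones with 4 df and on the log time axis. The smooth course lagged behind fast falls of the return, so positive sums of genes with such falls can be partly due to the fit.

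Across the 5545 genes, which are not independent replicates, the fitted changes of the shifts had a Pearson correlation of -0.29 and a Spearman correlation of -0.29. With measured in place of fitted changes these were 0.08 and 0.37, so the sign over all genes was not settled; measured changes without the raised arrays gave -0.32 and -0.11. Among the 76 genes called between low and high oxygen, a selection that favours opposite changes, the Pearson correlation was -0.865. Of 79 genes called after both shifts, 48 changed in opposite directions and 31 in the same direction, and independent lists would share 57.6.

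**Figure D4:**
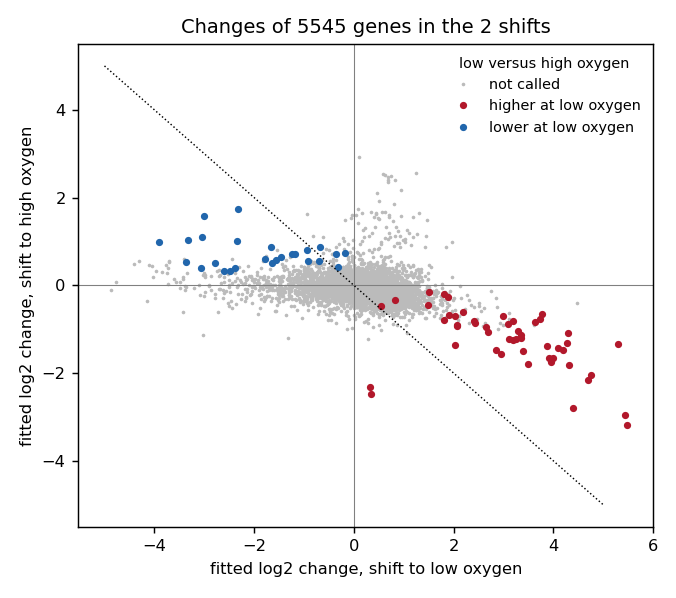
Fitted log2 change in the shift to high oxygen (vertical axis) against that in the shift to low oxygen (horizontal axis), 1 point per gene for 5545 genes; the dotted line is an equal return. Larger points are the 50 genes called higher (red) and the 26 called lower (blue) at low oxygen, with a Pearson correlation of -0.865.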

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

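Chosen after the result was seen were the tests of scanner background, oxygen level, mixed RNA, raised arrays, a trend with the intergenic level and a fading response, and the look at rising genes alone; the tests of genomic DNA, a short fall in oxygen and regroupings were fixed beforehand.

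The transitions differed in course for 1158 genes, a count that includes genes with an equal and opposite return. A sum of the 2 changes that differed from 0 was called for 641 genes. The genes with the largest F of the difference were PA3690 (106), PA1212 (95.3), PA0315 (85.0), PA3329 (83.9) and PA1214 (81.1). The largest sums were 4.06 for PA3431, 3.95 for ccpR, 3.81 for PA2310, 3.23 for PA3444 and 3.22 for PA3446, and -4.97 for PA3923, -4.69 for PA3922, -4.50 for PA2939, -4.16 for PA3516 and -4.03 for PA1914. The sizes for PA2310, PA3444 and PA3431 are uncertain. The signals of PA2310 and PA3444 lay below the intergenic median at 0 min of the shift to low oxygen, and that of PA3431 lay just above it. In data outside the comparisons, 37 of 199 intergenic probe sets were called after the shift to low oxygen with the intergenic median subtracted, and 45 as deposited. Between low and high oxygen limma called 0 either way. There 13 had an unadjusted p under 0.05 with the intergenic median subtracted, and 3 as deposited.

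Regroupings of the arrays were compared with the real counts, 100 each with the real one included. Permuted times gave as many calls as the real 2902 after the shift to low oxygen in 1 of 100, with 2661 as the highest other, and as many as 110 after the shift to high oxygen in 1 of 100, with 10 as the highest other. Other splits of the 12 arrays gave as many as 76 in 1 of 100, with 0 as the highest other. Transitions swapped at some times gave as many as 1158 in 4 of 100, with 1668 as the highest other, and permuted times as many as 641 in 4 of 100, with 2326 as the highest other. Each of the 5 counts ranked within 5 of 100, which does not exclude chance. Permuted times break up the serial order of samples from 1 culture. Other splits of the 12 arrays put the oxygen difference into the residual spread, so 0 calls there were likely in advance. Regroupings that called more than the real count, or nearly as many, point to a structure of the arrays.

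The first pattern is the raised intergenic signal of 8 arrays. Scanner background or unspecific hybridisation was looked for in probe sets for other strains. Their median signal was 0.917 times as high on raised as on other arrays, while the intergenic ratio was 2.16. These medians were 1.8 to 3.9 on raised and 1.7 to 6.3 on other arrays. So near to 0 their ratio says little, and this explanation stays open. Genomic DNA in the labelled material is a candidate explanation: the excess over dim gene probe sets correlated between raised arrays of the 2 transitions (median Spearman 0.632 over 15 pairs, 0.468 to 0.717; -0.006 between unraised arrays), although the labels describe a DNase step and transcription from all of the genome was not tested apart from it. Oxygen level cannot be told apart with 4 of 5 late arrays raised at low and 2 of 5 at high oxygen (two-sided Fisher's exact p = 0.524). What the raised arrays share beyond this stays open.

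The second pattern is on the low-to-high 40 min array, where 48 of the 50 genes higher at low oxygen lay above the mean of 35 and 50 min, 15 of them by more than 1 on the log2 scale; ccoN2 had 215 between 44.7 and 22.8, while the excess of arcC was -0.13. RNA of another array's sample is argued against by the mixed fractions implied by single genes. These spread by at least 1.33 times their median for each of 14 sources, where a simulated mixture gave 0.06 to 0.93. The simulated scatter came from an array with neighbours closer in time and left out the scatter of the source array, so it may be too small. With source signals of at least 1000, high-to-low 5 min gave 0.46 on 4 genes, so that source is not fully excluded. A short fall in oxygen predicted that the excess would follow the 5 min response better than the 60 min one, and the difference of Spearman correlations over 76 genes was -0.162 (bootstrap 95% interval -0.34 to -0.004). These genes were chosen by a fit that holds the 60 min array, and over the 50 rising ones alone, looked at afterwards, the order was the other way (0.786 and 0.661), so a fall in oxygen stays open. No other biological explanation was tested.

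The third pattern is the 641 genes whose fitted changes in the 2 shifts did not mirror each other. Without the 8 raised arrays the sum shrank to a median of 0.205 of its size, but that fit keeps 1 of 5 late arrays at low oxygen and extrapolates, and measured values of unraised arrays gave 0.976, but on genes chosen by a fit that holds those arrays, so neither test decides and the raised arrays stay open. With the intergenic median as a covariate 638 of the 641 sums kept call and sign (99.5%), and with it subtracted 579 (90.3%), which argues against a trend with that level as the whole cause. A response that fades by the steady state at low oxygen cannot be told apart: 80.3% of these genes lay nearer, at the start of the return, to their level before the first shift than to their late level at low oxygen, but choosing genes by their sum favours this. The smooth course also lagged behind fast falls of the return, which makes the fitted sums of such genes more positive. For the second cbb3 oxidase the measured late medians were 5.10 and -4.55 in the 2 shifts, against a median fitted sum of 2.305. How far this lag made up the positive sums was not tested. A drift of the culture between the 2 transitions was not tested either.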

How the results depend on the processing

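Chosen after the data were seen were the settings without the 8 raised arrays, with the intergenic median subtracted and with it as a covariate; the cause of a change was not tested unless stated.

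Counts of calls moved as follows. Quantile normalization gave 1829 genes with a different course, 1076 with a sum other than 0 and 143 between low and high oxygen. The covariate gave 175 after the shift to high oxygen, 1907, 1090 and 163. Without the raised arrays there were 72 sums (23 shared with the 641) and 13 between low and high oxygen, with fewer arrays by construction, and 19 lists after the shift to high oxygen. A spline of 4 df gave 347 sums, one of 2 df 44 genes after the shift to high oxygen, and log time 237 sums. Low versus high oxygen gave 657 without the transition term, 177 with 0 and 5 min as start and 826 on late arrays only, blocked by time, where oxygen and transition coincide (74 of the 76 among them). Alone, the transitions gave 1934 and 395. With an estimated correlation 1, 2 and 3 lists were called for low versus high, to low and to high oxygen, and fry called 11, 12 and 2 in the same order. Without 1 array at a time the ranges were 2449 to 3721 after the shift to low oxygen, 86 to 226 after the shift to high oxygen, 900 to 1589 for course, 419 to 1013 for sums, 17 to 451 for low versus high oxygen and 13 to 21 lists; the extremes 17 and 451 came from the 0 min arrays, 226 and 419 from the low-to-high 0 min array and 1013 from the low-to-high 5 min array. No paired analysis was possible because replicate numbers only order the arrays of a transition, apart from those late arrays paired by time.

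The correlation of the shifts (Pearson, Spearman) was 0.082 and 0.37 on measured changes, -0.211 and -0.159 after quantile normalization, -0.234 and -0.137 without the dimmest 25%, -0.14 and -0.106 without raised arrays, -0.323 and -0.113 on measured changes without them, and -0.116 and 0.167 on measured changes with the intergenic median subtracted.

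The direction of a named gene's change or of a list's camera test turned, with a call on at least 1 side, in these cases, given as medians for lists. Without raised arrays, where late low-oxygen values are extrapolated, PA2939 had 1.81 in the shift to low oxygen and a sum of 1.19, PA3690 had 0.58 (0.24 on log time), and the lists in the shift to low oxygen had 4.70 (hydrogen cyanide), 1.26 (TCA cycle), 0.97 (oxidative stress), 0.73 (pyoverdine), 1.92 (phenazines), 0.33 (quorum sensing) and 0.87 (ribosomal proteins). In the shift to high oxygen they had -0.22 (TCA cycle), -0.17 (NADH dehydrogenase), -0.10 (quorum sensing), -0.19 (heat shock), -0.078 (flagellum) and -0.12 (ribosomal proteins). Medians alone also changed sign there: 0.19 (first cbb3 oxidase), -0.63 (other terminal oxidases) and 1.52 (ATP synthase) to low oxygen; 0.30 (other terminal oxidases), 0.09 (pyochelin), 0.35 (other iron uptake), 0.16 (type III secretion) and 0.01 (pyocins) to high oxygen; and -0.09 (pyochelin) and -0.11 (pyocins) between low and high oxygen. Without the high-to-low 0 min array, phenazines had 0.37 and quorum sensing 0.23 between low and high oxygen, and without the low-to-high one ribosomal proteins had -0.14; over single arrays the ranges were -1.612 to 0.37, -1.252 to 0.23 and -0.14 to 0.183. Ribosomal proteins had 0.15 and -0.027 in the 2 shifts after quantile normalization and 0.14 and -0.018 with the covariate, and the TCA cycle -0.15 and -0.13 with the covariate. Of the 69 named genes in low versus high oxygen, 29 lost the call without raised arrays and 2 gained it, and 0 of these changed direction; groES (-0.10 to 0.26) and rpsE (-0.07 to 0.05), not called, changed sign. Dim genes near the intergenic signal of 15.6 to 69.6 are limited by it.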

Other observations

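All gene groups and single genes in this part were looked at after their values were seen, and nothing here was tested apart from the fits already described.

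Transcripts of heat shock proteins and proteases, which refold or remove damaged proteins, stood above the 0 min array in the median from 5 to 70 min of low oxygen, with no single peak. The median of the 12 genes was 1.82 above the 0 min array at 35 min of low oxygen, between 0.91 at 30 min and 0.93 at 40 min, 1.08 above it at 60 min and -0.78 at 90 min, and it lay between -0.77 and -0.04 from 5 to 90 min of the return. The chaperone gene groEL went up and down, with signals of 2482 at 0 min, 4956 at 15 min, 2075 at 30 min, 4189 at 35 min, 2350 at 40 min, 4213 at 60 min and 1336 at 90 min of low oxygen. At the same times the median signal of the rRNA probe sets was 4959, 7075, 2136, 4912, 2602, 5432 and 2176. The flagellum gene fliC had 2823, 4752, 2098, 4121, 2308, 3619 and 1941. Bright signals of an array thus moved together, and for groEL this cannot be told apart from a heat shock response. The alkyl hydroperoxide reductase gene ahpF went from 197 at 0 min to 1050 at 20 min and 76.6 at 90 min, and PA3690 from 176 to 2519 and 103. The arrays at 40 and 90 min were raised, while those at 15, 20, 25, 30, 35 and 60 min were not.

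Hydrogen cyanide genes moved both ways. Their median was -1.22 at 25 min of low oxygen, 1.18 at 60 min and 0.89 at 90 min, and 0.91 in the steady state at low oxygen against the first 0 min array. Pyoverdine genes stood at -1.30 in that steady state, the second cbb3 oxidase at 4.14 and Anr-associated genes at 1.33, while phenazines stood at 0 after -1.81 at 60 min, and quorum sensing genes at 0.08 after -1.07 at 60 min. These values come from arrays that were not raised, except the one at 90 min. Over 999 genes with a mean log2 value above 8, the root mean square difference between the steady state at low oxygen and the first 0 min array was 0.47, against 1.24 for 60 min of low oxygen.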
